A study of Mus musculus with 2 samples.

How the data were processed

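H3K9me3 was measured by ChIP-seq in midbrain of mice at postnatal day 0. Per the labels there were 2 biological replicates of 2 technical replicates each, from mice of both sexes pooled, and replicate 1 was made from 15 mice. Per the labels the size range was 300 to 500, without a unit, and both replicates were placed in 1 group on the basis of their descriptions. No control or input sample was part of the series, and a control library that the sources mention was not described and not analysed here.

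The deposited data were 4 peak lists in narrowPeak format on the mm10 build: 1 for each replicate, 1 for both pooled and 1 called replicated. Per the notes deposited with the samples, the lists of the replicates derive from alignments and from further files that are not described. The replicated list derives from the other 3 by a rule that is not stated. The aligner, the peak caller, their versions, the threshold and the read depth are not given in the sources used here. Each deposited peak has a score (whole numbers for display, not used in any test), a signal value (column 7 of the format), a −log10 p, a −log10 q and a summit position. The signal value is the enrichment that the authors' caller gave, in a unit and with a normalization that are not stated, so it was used only to rank and describe peaks. The −log10 p values of the authors' caller, no lower than 2.03 in the lists of the replicates, served to form stricter lists. Most peaks shared their −log10 p and signal value with others, so ties were broken at random when lists of equal length or quartiles were formed. At a q of 0.05 or less were 56.9% of the peaks of replicate 1, 43.8% of replicate 2, 67.2% of the pooled and 92.4% of the replicated list, so the lists hold peaks that a stricter threshold would remove. Because read counts were not used here, the depth behind a peak is unknown and no counting interval could be given.

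Choices of groups, tests, gene lists, alternatives and the rule for named genes were made before the data were examined. Analyses used chromosomes 1 to 19, X and Y, while peaks on unplaced and unlocalised scaffolds were only counted and ranked. Overlapping peaks of a list were merged, genes came from the GENCODE vM21 annotation, and sequence, gaps and repeats (soft-masked bases) came from the GRCm38 reference, of which mm10 is another name. Promoters reached 1 kb to either side of the annotated start of protein-coding genes, with 1 start per gene. Other transcript starts within a gene did not count as starts or promoters. Sequence classes were promoters, coding exons, 5′ and 3′ UTRs, introns and intergenic sequence, and a base could count in more than 1 of them.

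Overlap of the replicates, sequence classes, gene lists, gene starts and ends and sequence composition were tested by rotation, a permutation test. All peaks of a chromosome were shifted by 1 random offset along its gap-free sequence, 10000 times with seed 20. The two-sided p was 2 times the smaller tail, so the smallest p possible was 0.0002, and p-values were adjusted by the Benjamini-Hochberg method within each family of tests (20 gene lists, 6 sequence classes, 3 measures of overlap, 4 tests of gene ends, 2 of sequence composition, 3 of clustering). Clustering was tested by placing each peak at random on its chromosome 1000 times, with a smallest p of 0.002. An adjusted p under 0.05 counted as past the threshold. These tests treat chromosomes and peaks as given and ask whether their positions differ from chance, and with 2 replicates of 1 group no difference between groups of mice was tested. A gene list counted protein-coding members (and noncoding ones for imprinted genes) whose body overlapped a peak by 1 bp or more. The zinc finger list took genes by symbol (Zfp, Zkscan, Zscan, Zik, Zim, Zbtb or Znf with a number), without a check of DNA binding. One gene of the list for liver, muscle and epithelium had no match in the annotation and was left out, which left 30 of 31.

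Genes were named by a fixed rule. It took the 10 protein-coding genes with the most replicated peak sequence and a peak in both replicates, the 3 members with the most such sequence of each list past the threshold, and up to 3 members with a peak of every other list. A further 19 genes were always reported. Regions named were the 10 windows of 1 Mb with the most replicated peak sequence and the 5 replicated peaks with the highest signal value. Genes and families outside that rule are said to have been chosen after their values were seen.

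Alternatives were stricter lists (peaks at or above the median −log10 p of their list), the pooled list or either replicate's own list in place of the replicated one, and rotation along whole chromosomes with gaps. Others were an overlap of 50%, lists of equal length, autosomes alone, merging within 1 kb, promoters or gene ends of 5 kb, gene bodies with 5 kb on both sides, 500 bp of a gene covered, and lists matched on gene length in 50 bins. Genes of the length-matched lists were drawn singly, so their p-values ignore the grouping of genes and of peaks. For clustering, windows of 500 kb and 5 or more peaks were tried. The rotation tests were tested on simulated data, with 100 simulations for each case. With no planted signal 0% of gene lists were called, with peaks planted in 30 of 100 members 100% were called, and when 30% of peaks were shared a mean of 30.5% was recovered. Each simulated list held 100 of 2943 genes, drawn at random from some chromosomes, with 1000 rotations and p-values that were not adjusted. Simulated lists were not families of neighbouring genes, so the rate of false calls for such families was not measured. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.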

Results

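Histone H3 trimethylated at lysine 9 (H3K9me3), a modification found on silent heterochromatin, was mapped by chromatin immunoprecipitation and sequencing in midbrain of newborn mice. All samples belonged to 1 group of 2 biological replicates, and there was no treated or second tissue group. Replicate 1 was made from the midbrains of 15 mice and replicate 2 from an unstated number, with both sexes pooled in each. The data were 4 lists of peaks, that is of intervals where the modification was enriched: replicate 1, replicate 2, both pooled, and a replicated list chosen by the authors from the pooled one. Replicate 1 held 49178 peaks and replicate 2 held 23913, while the pooled list held 35185 and the replicated list 13824. On chromosomes 1 to 19, X and Y these covered 14.9 Mb, 6.74 Mb, 11.97 Mb and 6.61 Mb, or 0.564%, 0.255%, 0.452% and 0.25% of the gap-free genome. Peaks were short, with a median width of 245 bp, 236 bp, 268 bp and 398 bp in the same order. The number of reads behind each list was not given in the sources used here, so no counting error could be attached to a peak, and a gene without a peak was not shown to be without the modification. Values below refer to the replicated list on the mm10 build unless another list is named, positions are counted from 1, and n = 2 throughout.

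The first question was which kinds of genes carried the modification. Peaks were found more often than chance gives in the clustered protocadherins, adhesion proteins of which each neuron expresses its own combination. Peaks were also found more often in genes with a zinc finger symbol, in receptors for pheromones and bitter taste, and in imprinted genes, which are expressed from 1 parental copy. Nearly all clustered protocadherins held one, whereas most zinc finger and receptor genes did not. At least 1 replicated peak lay in the body of 50 of 56 clustered protocadherin genes, 29 of 50 imprinted genes and 124 of 460 zinc finger genes. The corresponding counts were 46 of 120 type 2 vomeronasal receptors, 41 of 206 type 1 vomeronasal receptors and 5 of 35 type 2 taste receptors. Across the genome 1711 of 21911 protein-coding genes, or 7.81%, held such a peak. Genes that overlap could share a peak, as in the clustered protocadherins and for the imprinted Airn and Igf2r. The counts are therefore of genes, not of separate places with the modification.

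**Figure D1:**
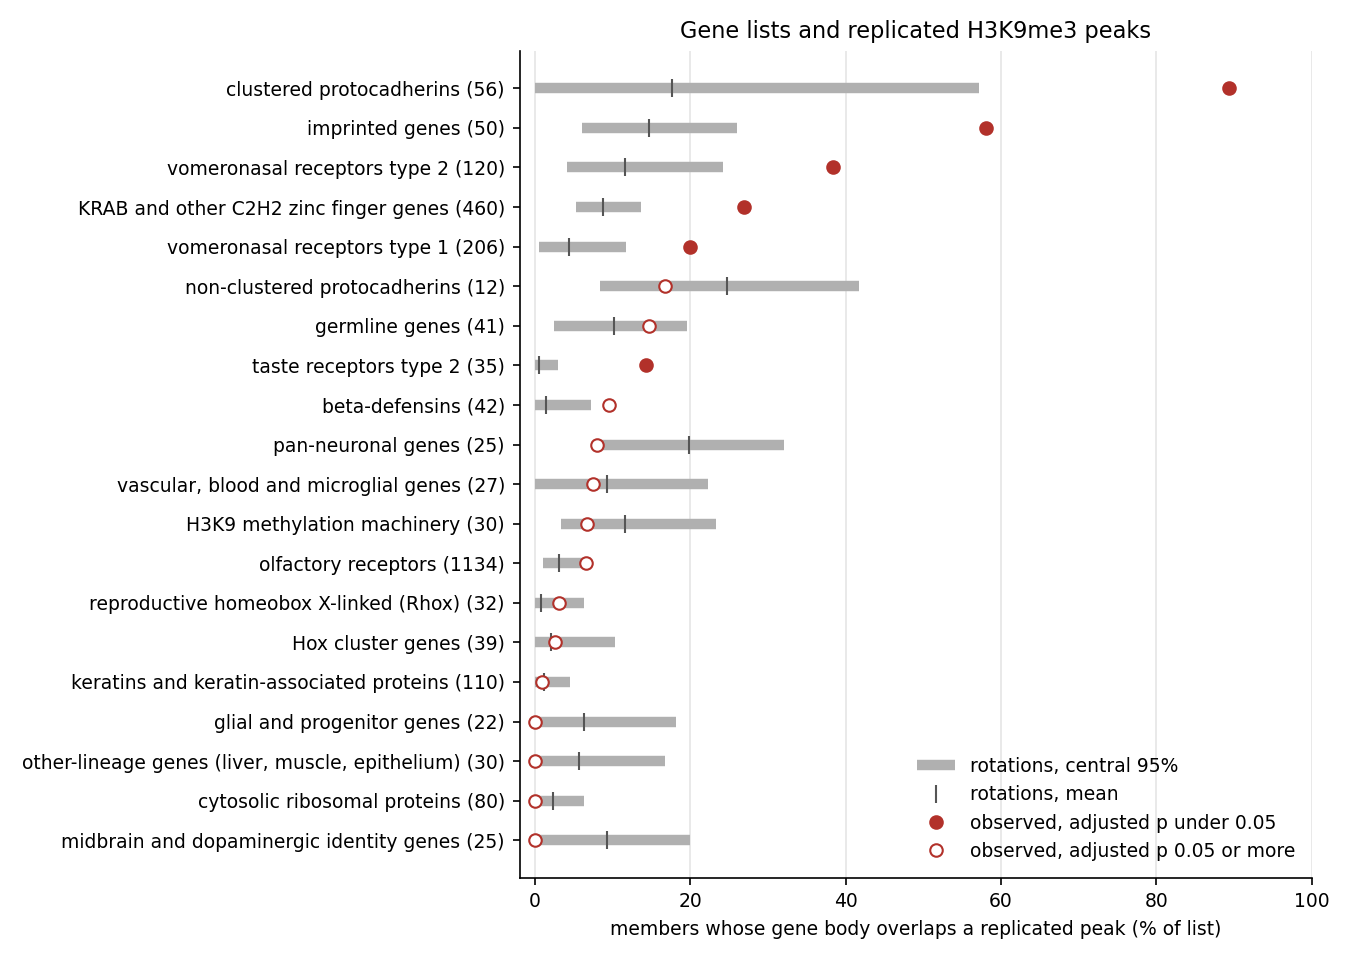
Percent of the members of each of 20 gene lists whose gene body overlapped a replicated peak (circles), beside the mean (tick) and central 95% (grey bar) of 10000 rotations of the peaks. Members per list are in parentheses; filled circles mark the 6 lists with an adjusted p under 0.05, among them the clustered protocadherins with 50 of 56 members.

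Each count was compared with rotations of the peaks along their chromosomes, a permutation that keeps the spacing of peaks and the length and grouping of genes. Rotated peaks reached a mean of 9.87 clustered protocadherins, 7.36 imprinted genes and 40.2 zinc finger genes, and the adjusted two-sided permutation p was 0.002 for all 3 lists. They reached a mean of 13.8 type 2 vomeronasal receptors (adjusted permutation p = 0.002), 8.92 type 1 vomeronasal receptors (adjusted permutation p = 0.0032) and 0.175 taste receptors (adjusted permutation p = 0.0167). All 6 lists also passed the threshold with the peaks of replicate 1 alone and with those of replicate 2 alone, so the direction was shared by 2 of 2 replicates. With replicate 1 alone the counts were 56, 43, 182, 61, 57 and 8, and with replicate 2 alone 50, 31, 155, 51, 46 and 7, in the order protocadherins, imprinted, zinc finger, vomeronasal type 2, vomeronasal type 1 and taste. The call for the taste receptors rested on 5 genes, all on chromosome 6, and was lost among the stronger peaks, where 2 of them held a peak (adjusted permutation p = 0.0807). It was lost as well when 500 bp of the gene had to be covered (adjusted permutation p = 0.147) and with 5 kb added on both sides of the gene (adjusted permutation p = 0.0698).

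The clustered protocadherins formed the most heavily covered region of the genome. Their large variable exons, which encode the extracellular part of each protein, lay on chromosome 18 from 36930285 to 37822134, and 50 of the 56 held a replicated peak. In the alpha cluster 11 of 13 exons held one, and the exceptions were those of Pcdhac1 and Pcdhac2. In the beta cluster 21 of 22 did, all but Pcdhb9, whose exon did hold a peak of replicate 1 and one of replicate 2. In the gamma cluster 18 of 21 did, the exceptions being Pcdhgc3, Pcdhgc4 and Pcdhgc5, the last of which held a peak of replicate 1. Replicated peaks covered 56.9% of the alpha, 52.7% of the beta and 77.0% of the gamma exon sequence. The values were 60.4%, 56.0% and 76.9% in replicate 1 and 41.1%, 29.3% and 64.8% in replicate 2. The exons without a replicated peak were named after their values were seen.

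**Figure D2:**
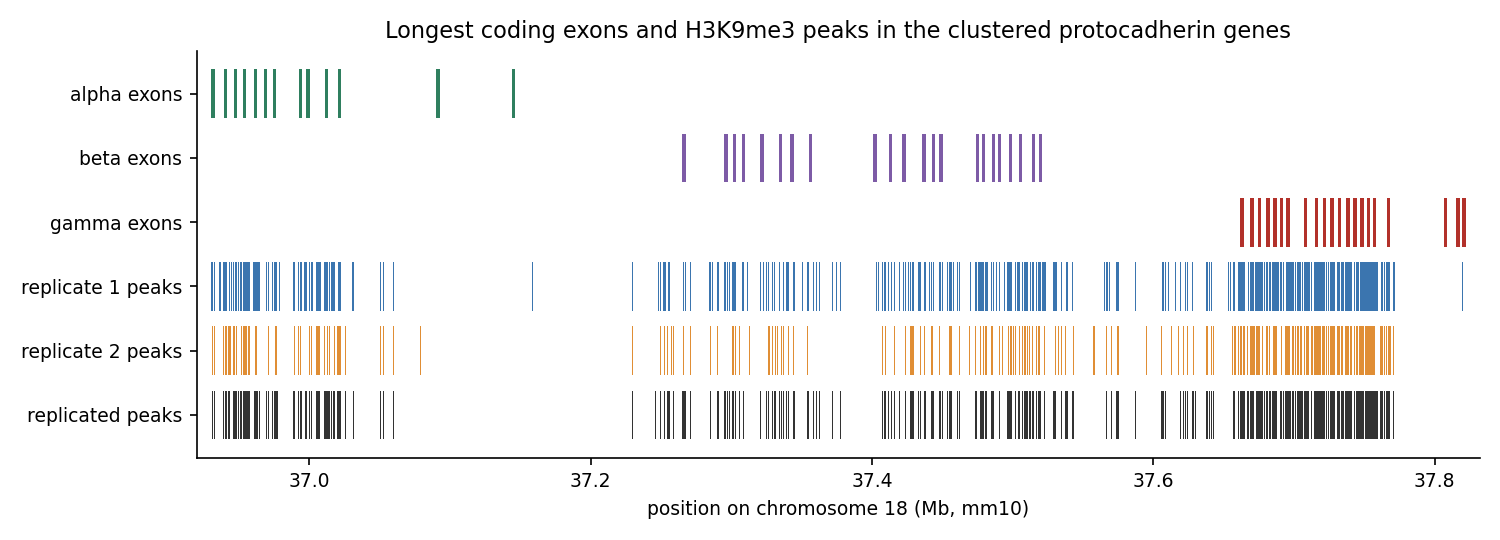
Position on chromosome 18 (Mb, mm10) of the longest coding exon of each clustered protocadherin gene, by cluster, and of the peaks of replicate 1, replicate 2 and the replicated list. Peaks lay both on the exons and between them, and 50 of the 56 exons held a replicated peak.

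The 10 protein-coding genes with the most covered sequence were all in this region, and their values overlap because the genes of a cluster share their last exons. Gm42416, Gm37013 and Gm37388 are annotated across most of the region, and replicated peaks covered 220026 bp, 212038 bp and 210006 bp of them. Pcdhga1 (ENSMUSG00000103144.1, chromosome 18, 37661793 to 37841873) held 81154 bp, or 45.1% of its body, with 79387 bp in replicate 1 and 66281 bp in replicate 2. Next came Pcdhga2 with 77158 bp, Pcdhga3 with 72629 bp, Pcdhgb1 with 68203 bp, Pcdhga4 with 64712 bp, Pcdhgb2 with 61028 bp and Pcdhga5 with 57504 bp. The strongest peak in all of them, at 37755080 to 37758562, lay over the promoter and coding exon of Pcdhga11 and had a signal value of 8.42. The non-clustered protocadherins, with 2 of 12 members against a rotated mean of 2.97, did not pass the test (adjusted permutation p = 0.792). Their 2 members were Pcdh9 with 1032 bp and Pcdh15 with 799 bp, the strongest peak of each in an intron.

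Zinc finger genes with a peak were spread over 16 chromosomes, with 27 of the 124 on chromosome 7. Zfp981 (ENSMUSG00000056300.14, chromosome 4, 146502027 to 146539395) had the most covered sequence, at 12809 bp, with 13209 bp in replicate 1 and 10126 bp in replicate 2. Zfp873 (ENSMUSG00000061371.7, chromosome 10, 82048123 to 82064745) was covered over 66.3% of its body, at 11013 bp, and its strongest peak lay over coding exon and 3′ UTR. Zfp369 (chromosome 13, 65278814 to 65304221) held 10651 bp. The strongest peaks of Zfp981 and Zfp369 lay in introns.

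Among imprinted genes Gnas, which encodes the stimulatory G protein alpha subunit (ENSMUSG00000027523.19, chromosome 2, 174284320 to 174346744), held 7 replicated peaks and 4490 bp, with 4270 bp in replicate 1 and 2403 bp in replicate 2. Trappc9 followed with 3725 bp, and Grb10, an adaptor that restrains insulin and growth factor signalling, with 2885 bp. The strongest peak of Grb10 lay in an intron. Snrpn held 1605 bp of replicated peaks, but 9608 bp in replicate 1, 2538 bp in replicate 2 and 6181 bp in the pooled list, more than Gnas in each of these 3. Kcnq1ot1 held 1520 bp, Peg10 1341 bp and Mest 1298 bp. Airn, the noncoding RNA antisense to Igf2r, had a 1152 bp peak across its start (chromosome 17, 12741110 to 12742261) that overlapped a peak of each replicate. A 259 bp peak lay in the promoter of Zrsr1 and overlapped both replicates, whereas the promoter peaks of Nnat, 642 bp, and Peg3, 260 bp, overlapped replicate 1 alone. Peaks of replicate 1 and replicate 2 covered 1314 bp and 809 bp of Peg3, most of it outside the replicated peak. H19 held no peak of any list in its body. Plagl1 held no replicated peak and none of replicate 2, but 228 bp in replicate 1 and 438 bp in the pooled list. Peaks of replicate 1 and replicate 2 lay 1224 bp and 2624 bp from the H19 start, and the nearest replicated peak lay 154323 bp away.

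Of the type 1 vomeronasal receptors with a peak, 28 were on chromosome 7, where Vmn1r73 held 6085 bp, Vmn1r68 3722 bp and Vmn1r72 2893 bp. Of the type 2 receptors with a peak, 22 were on chromosome 17, and the family was led by Vmn2r60 with 7851 bp, Vmn2r93 with 5296 bp and Vmn2r17 with 5049 bp. Among bitter taste receptors Tas2r104 held 752 bp, or 82.7% of its body, Tas2r130 461 bp and Tas2r121 341 bp. Olfactory receptors, the largest family in the genome, held a peak in 74 of 1134 genes against a rotated mean of 35.3 and did not pass the test (adjusted permutation p = 0.214). Their most covered members were Olfr398 with 3132 bp, Olfr139 with 3006 bp and Olfr77 with 2477 bp. The family did pass with the pooled list (adjusted permutation p = 0.0449), replicate 1 alone (adjusted p = 0.0171), replicate 2 alone (adjusted p = 0.0498) and against lists matched on gene length (adjusted p = 0.000667), always with more genes hit than by chance.

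Lists of genes of midbrain, glial and other cell types were tested as well, while expression itself was not measured. None of 25 midbrain and dopaminergic identity genes held a replicated peak, against a rotated mean of 2.33 (adjusted permutation p = 0.288). This included Th, the tyrosine hydroxylase gene, and En1, a homeobox gene of the midbrain, which held no peak of any list. With replicate 2 alone the same count of 0 did pass (adjusted permutation p = 0.0109, rotated mean 4.82), while with replicate 1 alone 3 of the genes held a peak and the test was not passed (adjusted permutation p = 0.0876, rotated mean 7.09). No replicated peak lay in the 80 cytosolic ribosomal protein genes (rotated mean 1.87, adjusted permutation p = 0.514) or the 22 glial and progenitor genes (1.40, adjusted permutation p = 0.614). The same held for the 30 genes of liver, muscle and epithelium (1.72, adjusted permutation p = 0.526). In that order, 3, 2 and 3 genes were hit with replicate 1 alone and 0, 4 and 3 with replicate 2 alone, none past the threshold. Of the glial and progenitor genes 2 held a peak in each replicate. For the genes of liver, muscle and epithelium the count of 0 did pass with the pooled list (rotated mean 4.14, adjusted permutation p = 0.0449). The housekeeping genes Actb and Gapdh held none in any list. Pan-neuronal genes were hit in 2 of 25 cases against 4.95 (adjusted permutation p = 0.287), by a 318 bp peak in Syt1 and a 280 bp peak in Nrxn1. The Nrxn1 peak overlapped replicate 1 alone. With replicate 1 alone 11 pan-neuronal genes were hit against 12.4 (adjusted permutation p = 0.722), and with replicate 2 alone 6 against 8.62 (adjusted permutation p = 0.386). Vascular, blood and microglial genes were hit in 2 of 27, Pdgfrb and Tek, against 2.49 (adjusted permutation p = 1).

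Germline genes, which are silent in somatic tissue, held a peak in 6 of 41 cases against a rotated mean of 4.18 (adjusted permutation p = 0.614). Ddx4, a germ cell RNA helicase, had a 1129 bp promoter peak on chromosome 13, 112651626 to 112652754, that overlapped both replicates. The promoter peak of Dazl, 390 bp, overlapped replicate 1 alone, Hsf2bp held 693 bp and Zpbp 362 bp, and Asz1 and Sycp3 held no peak in any list. Beta-defensins were hit in 4 of 42 cases (rotated mean 0.576, adjusted permutation p = 0.12). The family was led by Defb33 with 2136 bp, Defb4 with 790 bp, in a peak that overlapped replicate 1 alone, and Defb8 with 669 bp. That family passed with the pooled list (adjusted permutation p = 0.0449) and replicate 1 alone (adjusted permutation p = 0.0413) but not with replicate 2 alone (adjusted permutation p = 0.194). The Hox genes (Hoxa11 alone, rotated mean 0.796, adjusted permutation p = 0.968), keratins (Krt9 alone, 1.29, adjusted permutation p = 1) and Rhox genes (Rhox13 alone, 0.242, adjusted permutation p = 0.514) each had 1 member with a peak. The peaks of Hoxa11 and Krt9 overlapped replicate 1 alone. With replicate 1 alone 10 Hox genes were hit against 3.29 (adjusted permutation p = 0.0592). With replicate 2 alone 6 were hit against 1.88 (adjusted permutation p = 0.143). Of the 30 genes of the H3K9 methylation machinery Atf7ip and Smchd1 held 1 peak each, against 3.48 (adjusted permutation p = 0.774). The replicated peak of Smchd1 overlapped replicate 1 alone. With replicate 1 alone 5 genes of the H3K9 list were hit against 11.7 (adjusted permutation p = 0.0265) and with replicate 2 alone 2 against 7.28 (adjusted permutation p = 0.0445), both below chance.

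The second question was where along these genes the modification lay. Peaks lay at the 3′ end of zinc finger genes, where the exon coding for the zinc fingers usually is, more often than chance gives. A replicated peak lay within 1 kb of the 3′ end of 65 of 460 zinc finger genes, 8.15 times the mean of the rotations (7.97; adjusted permutation p = 0.0008). Only 4 had one within 1 kb of the annotated gene start, against a rotated mean of 7.93 (adjusted permutation p = 0.506). In replicate 1 alone the 3′ ends of 85 and the starts of 18 zinc finger genes had a peak, and in replicate 2 alone 69 and 2. The starts fell below chance with replicate 2 alone (adjusted permutation p = 0.0272), and within 5 kb the direction turned, with 40 starts against a rotated mean of 21.7 (adjusted permutation p = 0.168). Zfp180 (chromosome 7, 24103778 to 24107569) had the strongest replicated peak in any protein-coding gene of the chromosomes, with a signal value of 8.68, over its coding exon and 3′ UTR. Among the other 21451 protein-coding genes 323 starts and 334 ends had a peak, against a rotated mean of 251 for each (adjusted permutation p = 0.0419 and 0.0296). Those calls were lost with either replicate's own list, where the counts were 0.938 to 1.13 times the rotated mean.

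Over all genes, coding exons were the sequence class most enriched for the modification and introns the most depleted. Coding exons made up 5.90% of replicated peak sequence against 1.58% in rotated peaks, a ratio of 3.73 (adjusted permutation p = 0.00024). Zinc finger genes supplied 22.5% of that coding sequence and the clustered protocadherins 22.2%, with 3.94% from olfactory receptors, 1.49% from type 1 and 0.36% from type 2 vomeronasal receptors. With those 5 families left out, a test chosen after the values were seen, the ratio was 2.08 (permutation p = 0.0002). Promoters held 3.44% of peak sequence, 1.89 times the rotated mean, 3′ UTRs 2.42%, 1.71 times, and 5′ UTRs 0.546%, 1.62 times (adjusted permutation p = 0.00024, 0.00024 and 0.002). Intergenic sequence held 68.3% against 58.7% in rotated peaks, and introns held 23.1% against 37.98% (adjusted permutation p = 0.00024 for both). The direction was the same in both replicates, where the ratio for coding exons was 2.61 and 2.94 and that for introns 0.631 and 0.668.

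**Figure D3:**
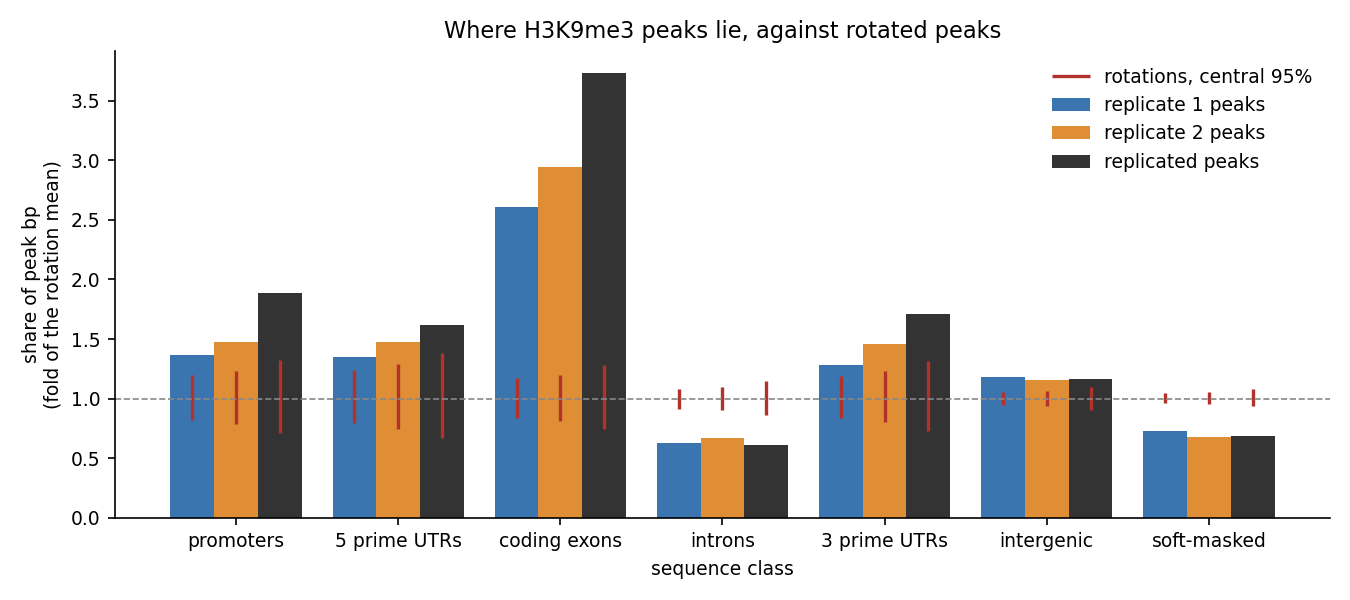
Share of peak sequence in each class as a fold of the mean of 10000 rotations, for replicate 1, replicate 2 and the replicated list, with the central 95% of the rotations as red lines. Coding exons stood highest, at 3.73 in the replicated list, and introns lowest among the gene parts.

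Peaks held less repeat sequence and slightly more G and C than rotated peaks. Bases marked as repeats in the reference made up 23.3% of replicated peak sequence against 34.0% in rotated peaks, and G and C made up 45.2% against 42.2% (adjusted permutation p = 0.0002 for both, the smallest that 10000 rotations can give). Repeat shares were 25.3% in replicate 1 and 23.0% in replicate 2.

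The third question was whether the modification lay in clusters. The 10 windows of 1 Mb with the most covered sequence held 18.7% of all replicated peak sequence. The genes given for a window are those it contains, and peaks in it also lay outside them. The protocadherin window on chromosome 18, 37000001 to 38000000, held 203 kb, with 216 kb in replicate 1 and 149 kb in replicate 2, and ranked first in each. The window on chromosome 4, 144000001 to 145000000, with Prame-like and oogenesin genes of the germline such as Pramel4 and Oog3, held 141 kb. The window on chromosome 12, 114000001 to 115000000, held 140.0 kb and no protein-coding gene, but 49 variable segments and 39 variable pseudogenes of the immunoglobulin heavy chain, which are joined in B cells to make antibodies. On chromosome 7, the windows from 17000001 to 18000000 and from 18000001 to 19000000 held 135 kb and 107 kb and contain pregnancy-specific glycoprotein and Ceacam genes, and that from 33000001 to 34000000 held 105 kb and contains secretoglobins. The window on chromosome 13, 61000001 to 62000000, which contains the placental cathepsins, held 118 kb. The other 3 windows contain vomeronasal receptor genes: chromosome 7, 10000001 to 11000000 with 103 kb, chromosome 7, 12000001 to 13000000 with 95.3 kb, where 9 genes of the zinc finger list also lay, and chromosome 17, 20000001 to 21000000 with 92.4 kb. The genes and families named as lying in these windows, and Zfp180 and Pcdhga11 above, are those found at regions picked by rank.

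A replicated peak had its nearest neighbour at a median distance of 2204.5 bp, against 48359 bp when each peak was placed at random on its chromosome (adjusted permutation p = 0.002, the smallest that 1000 placements can give). The distances were 2834 bp in replicate 1 and 6383 bp in replicate 2, against 16387 bp and 32154 bp. Random placement also sets apart pieces of 1 enriched stretch, so the test does not tell clusters of stretches from 1 stretch called in pieces. Merging within 1 kb left 9800 of 13615 replicated peaks. Windows with 10 or more peaks were fewer than random placement gave, 147 against 343 (adjusted permutation p = 0.002). The share of peaks in such windows, a measure added after that count was seen, was 63.0% against 38.2% at random (adjusted permutation p = 0.002). That share fell below random in replicate 1 alone, at 88.1% against 96.6% (adjusted permutation p = 0.002), and was 60.2% in both the data and the random placements of replicate 2 (adjusted permutation p = 0.909). Covered sequence per window had a Spearman correlation of 0.647 between the replicates across 2737 windows, which are not independent replicates.

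Of the 5 strongest replicated peaks by signal value a pair was on unplaced scaffolds, where no genes were assigned here, at 9.98 and 9.41, and a pair lay in the noncoding transcript Gm49692 on chromosome 12, at 20229639 to 20234447 and 20226798 to 20228314, with 9.38 and 8.91. The remaining one was that of Zfp180.

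By chromosome, replicated peaks were densest on 7 and 17 and least dense on X and Y. Replicated peaks covered 9.80 kb per Mb of chromosome 7, 6.13 kb of 17, 4.83 kb of 4 and 4.01 kb of 18, against a mean autosome of 2.76 kb ± 2.19 (SD across 19 autosomes). Chromosome 14 was lowest among autosomes at 0.973 kb, X held 0.643 kb and Y 0.0543 kb, where repeats made up 46.8% and 96.3% of the sequence. In replicate 1, however, X was denser than 16 of 19 autosomes. Chromosome 7 was also the highest in each replicate, at 15.7 kb and 7.65 kb, and chromosome 14 the lowest autosome, at 3.31 kb and 1.57 kb.

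**Figure D4:**
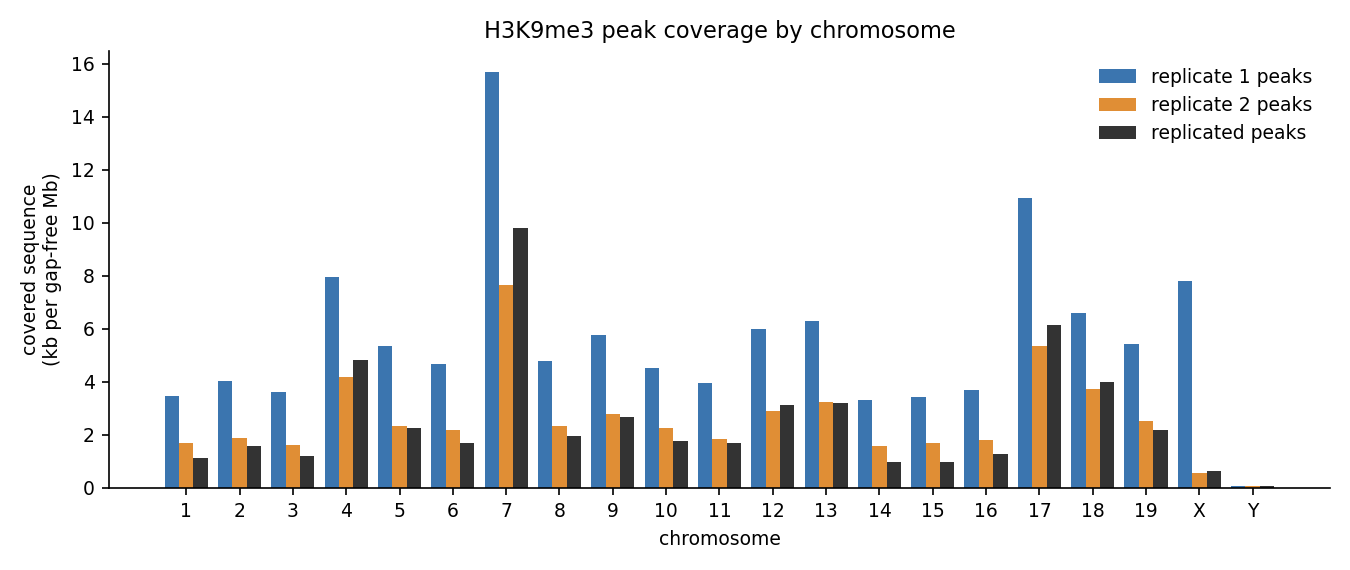
Sequence covered by peaks, in kb per gap-free Mb of each chromosome, in replicate 1, replicate 2 and the replicated list. Chromosome 7 was highest in all 3, and X differed between the replicates, at 7.79 kb in replicate 1 and 0.542 kb in replicate 2.

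Chromosome X differed between the replicates. Replicate 1 had 4867 peaks there, 9.96% of its list, and replicate 2 had 317, 1.34% of its list. The density on X was 1.35 times the mean autosome in replicate 1 and 0.192 times in replicate 2, with 0.428 times in the pooled and 0.233 times in the replicated list. In replicate 1 the ratio was 1.03 in its stricter list and 0.947 for as many of its strongest peaks as replicate 2 had, with equally strong peaks at the end of that list taken at random. With those equally strong last peaks left out it was 0.778. Both lists were chosen after the values were seen. In replicate 1, 2.42% of X peaks overlapped a peak of replicate 2, against 23.0% of autosomal peaks, a share limited by the few X peaks of replicate 2. In replicate 2, 40.7% of X peaks overlapped a peak of replicate 1, against 44.3% of autosomal peaks.

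The last comparison was between the replicates. They shared far more peaks than chance gives, most of all among strong peaks, but most peaks of replicate 1 were not called in replicate 2. Of the peaks on chromosomes, 10237 of replicate 1, or 20.9%, overlapped a peak of replicate 2 (rotated mean 0.635%), and 10468 of replicate 2, or 44.3%, overlapped one of replicate 1 (rotated mean 1.302%). The covered sequence common to both was 0.141 of their union against 0.0023 in rotations, and the adjusted permutation p was 0.0002 for all 3 measures. When replicate 1 was limited to as many of its strongest peaks as replicate 2 had, 30.4% and 32.6% were shared.

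Sharing rose with the strength of the peak. In replicate 1, 11.7% of the lowest quartile of peaks by signal value and 40.2% of the highest quartile were shared, and in replicate 2 31.4% and 64.1%. Among 10237 overlapping pairs the signal values of the replicates had a Spearman correlation of 0.19 and a Pearson correlation of 0.264, across peaks, which are not independent replicates.

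All 13824 replicated peaks were unchanged entries of the pooled list, 39.3% of it. Of those on chromosomes, 94.97% overlapped a peak of replicate 1 and 73.8% a peak of replicate 2. Both were overlapped by 69.3%, and 69 peaks, 0.507%, overlapped neither. From the other side, 28.4% of replicate 1 peaks and 46.9% of replicate 2 peaks overlapped a replicated peak.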

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

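Among the tests in this part, the comparison of the X ratio between replicates at equal length, the repeat share that gaps need by composition, the share of replicated peaks overlapping both replicates and the share of stronger peaks left out were chosen only after the result was seen. The other tests had their limits set before their outcome was seen, although the equally long list for X was chosen after the X values were seen. No biological explanation was tested for any pattern, since all samples form 1 group.

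Peaks outside the main measurement were found on unplaced and unlocalised scaffolds, which entered no test. There were 310 such peaks in replicate 1, 269 in replicate 2, 278 in the pooled list and 209 in the replicated list, where they covered 197 kb. Their median width in the replicated list was 615 bp against 396 bp on chromosomes, and 13 of the 101 strongest replicated peaks, ties included, lay there.

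Chromosome X held 4867 peaks of replicate 1 and 317 of replicate 2. The longer list of replicate 1 does not account for the whole of this: with as many of its strongest peaks as replicate 2 had, its ratio of X to the mean autosome fell to 0.947, which was still 4.92 times the ratio of replicate 2. The ratio itself fell between the limits set beforehand and decided nothing, so this rests on the comparison with replicate 2, chosen afterwards. With the equally strong last peaks left out, also a choice made afterwards, the ratio was 0.778, against 0.192 in replicate 2. The X peaks of replicate 1 were weaker than its list as a whole. Their median −log10 p was 4.11 against 4.79, and their median signal value 3.08 against 3.36. An offset of the whole chromosome between the immunoprecipitated and control libraries of replicate 1 would spread peaks evenly along X. The ratio of variance to mean of peaks per window was 25.4 on X, lower than the autosomal median of 40.3 but above 6 of 19 autosomes. For clustered peaks this ratio can rise with the mean count, which was 31.2 on X and 11.7 to 14.5 on those 6. So an offset cannot be told apart from real peaks, and the control and the read counts that would settle it were not analysed here. A different mix of the sexes in the pools, or a difference in the X chromosome itself, stays open and untested.

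Replicated peaks held less repeat sequence than rotated peaks. Gaps of at most 5 kb between neighbouring peaks were rich in repeats, at 41.0% against 34.0% (31.0% to 37.96%) in rotations (permutation p = 0.0008). This decides nothing, since peaks with 22.6% repeats in surroundings with 34.7% leave 41.5% for the gaps between them. The tables argue against peaks lying in surroundings with few repeats, since the 5 to 50 kb around them held 34.7% repeats against 33.8% in rotations. Reads that were not placed in repeats, breaking the modification into separate peaks, cannot be told apart from a real absence of the modification there.

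The replicated list held pooled peaks that were not found in both replicates. Overlap with both by 50% of either peak was not the whole rule, since 68.5% of replicated peaks met it, although all 9326 pooled peaks that met it were kept. Strength alone was not the rule for the other 4289 either, since 11.6% of the 21292 peaks left out were stronger than the median of those 4289. That share was chosen after the result was seen. The area under the curve of −log10 p between the same groups was 0.782. It fell between the limits set beforehand and decided nothing. A rule that uses peaks called on parts of the reads stays open, as those lists were not analysed here.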

How the results depend on the processing

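Alternatives chosen only after the data were seen were the equally long list for X with and without its tied last peaks, coding exons without 5 gene families, the share of peaks in crowded windows and the covered sequence of each named gene under other lists. All others were planned. That covered sequence differed from the replicated list by more than the spread between the replicates in 60 of 186 comparisons over 62 genes. It was larger for 12 genes with the pooled list, larger for 13 and smaller for 4 without replicate 2, and larger for 5 and smaller for 26 without replicate 1. Over 38 tested results 256 alternatives were run, of which 213 kept the direction and the side of the threshold. A call was lost in 15 alternatives, 6 of them with the direction turned as well, and gained in 11. In 23 alternatives the direction turned: the 6 just named, 15 where neither value was past the threshold and 2 where both were. No alternative changed the calls for clustered protocadherins, zinc finger genes and their 3′ ends, imprinted genes, vomeronasal receptors of both types, the 6 sequence classes, repeats, GC, the overlap of the replicates or the distance between peaks. Read depth, which limits how many peaks can be called, is not given, so its effect was not measured. The cause was not tested for any of the changes that follow, apart from counts that fell because fewer peaks were used.

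With stricter lists the peaks numbered 26398 in replicate 1, 15425 in replicate 2, 18178 pooled and 6777 replicated. Requiring an overlap of 50%, replicated peaks were found in replicate 1 in 90.3%, in replicate 2 in 60.1%, in both in 51.9% and in neither in 1.53%. Sharing of the lowest quartile of replicate 1 peaks by strength became 8.51% with 50% of the shorter peak, 12.99% on autosomes and 13.3% with stricter lists, and that of the highest quartile 34.97%, 43.3% and 42.3%. For replicate 2, 50% of the shorter peak gave 24.4% and 57.03%, and stricter lists 58.4% in the highest quartile.

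Without 1 replicate the X ratio ranged from 0.192 to 1.35, reversed at its upper end, and chromosome 7 from 7.65 to 15.7 kb per Mb. The ratio of replicate 1 itself was 1.03 with its stricter list, 0.947, below 1, in a list as long as that of replicate 2 with ties taken at random, and 0.778 with the tied last peaks left out.

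Ratios of gene lists to their rotated means changed as follows. Olfactory receptors passed the threshold with the pooled list (1.94), without 1 replicate (1.82 to 1.93) and with length-matched lists (1.77), which ignore the grouping of genes. Beta-defensins passed with the pooled list (5.02) and without replicate 2, with a range of 3.11 to 3.89. Taste receptors no longer passed with stricter lists (23.2), 5 kb flanks (7.56) or 500 bp covered (35.3). Depletion passed for midbrain identity genes without replicate 1 (0 to 0.423), for the genes of liver, muscle and epithelium with the pooled list (0) and for the H3K9 machinery without either replicate (0.275 to 0.428). Lists that failed the test in every setting changed direction: non-clustered protocadherins (1.02 with 500 bp), Hox genes (0 with stricter lists and 500 bp, 0.612 length-matched), keratins (1.05 to 1.54 without 1 replicate), Rhox genes (0.792 pooled, 0.961 length-matched, 0.840 to 2.95 without 1 replicate), germline genes (0.977 stricter), glial genes (0.396 to 1.297 without 1 replicate) and vascular genes (1.63 stricter, 1.86 with 500 bp). The H3K9 machinery also did so with stricter lists (1.12). For Hox genes the ratio rose from 1.26 to 2.71 pooled, 2.53 with 5 kb flanks and 3.04 to 3.19 without 1 replicate, none past the threshold.

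At zinc finger starts the ratio was 1.84 within 5 kb, reversed, and 0.175 to 0.890 without 1 replicate, past the threshold at the lower end. For other genes the starts gave 0.949 pooled, 0.882 within 5 kb and 0.938 to 1.03 without 1 replicate, and the ends 1.08, 1.05 and 0.962 to 1.13, none of them past the threshold. Windows with 10 or more peaks numbered 99 with stricter lists and 172 with 500 kb windows, where the mean of random placements was 165, and neither count was past the threshold. The share of peaks in such windows was 74.4% pooled and 60.2% to 88.1% without 1 replicate, and 75.2% with windows of 5 or more peaks. The pooled value and the upper end were below random and past the threshold, while the lower end and the value for 5 or more peaks were within the random range.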

Other observations

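The families in this part were chosen after the most covered windows were seen, so their counts were not tested. Placental cathepsins, proteases made by trophoblast cells, held a replicated peak in 8 of 8 genes, and Ceacam genes in 7 of 15. Pregnancy-specific glycoproteins held one in 4 of 13 genes, secretoglobins in 10 of 34, Prame-like genes in 4 of 16 and genes related to formyl peptide receptors in 2 of 7, the last being Fpr3 and Fpr-rs3. For cathepsins, Ceacam genes and pregnancy-specific glycoproteins the counts were 8, 9 and 6 in replicate 1 and 8, 9 and 5 in replicate 2. For secretoglobins, Prame-like genes and formyl peptide receptor relatives they were 10, 8 and 2, and 8, 4 and 3. Most of these are families in which copies of a gene lie side by side and which act outside the brain, in placenta, gonads, glands or immune cells.

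Of the heavy chain variable segments of the antibody genes 24 of 113 held a replicated peak, with 38 in replicate 1 and 21 in replicate 2, and of the kappa light chain segments 0 of 100 did, with 1 in each replicate. A group of 23 cadherin genes outside the protocadherins held a peak in 5 genes, with a total of 4.32 kb, in 13 with replicate 1 and in 16 with replicate 2.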
